A study of Rattus norvegicus with 33 samples.

How the data were processed

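Total RNA of rat mammary glands was biotin-labelled and hybridised to Affymetrix whole-transcript arrays, 33 in all. The authors deposited 1 table of log2 values for 36685 probe sets, made with Affymetrix Expression Console and RMA (robust multi-array average, which corrects background, normalizes across arrays and summarises probes), per the submitters' processing notes; the versions are not given in the sources used here. The deposited log2 values lay between 2.405 and 14.228 with 0 missing, and values near the top, such as casein genes in lactation, can be compressed by saturation. The table has no detection calls, so low values have no stated limit. The number of arrays limits the precision of each group value.

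Probe sets were named from the platform annotation: 18511 had 1 gene symbol, 575 had several and 17599 had none listed. Of the 18511, 18394 matched an entry of a RefSeq gene table by gene identifier; the table was used for names only, and no coordinates are given because the sources used here name no genome build. Only probe sets with exactly 1 symbol were tested. Of the 18166 symbols, 291 had more than 1 probe set, and the probe set with the highest mean over all arrays was kept. A gene was tested where its value exceeded 7.645, the median over single-symbol probe sets, in at least 3 arrays, which left 10986 genes. Ratios that involve a group below that floor are less exact than others. No arrays were duplicates of each other.

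The groups were taken from the developmental stage in the labels, and batch and extraction kit from the labels as well. All arrays of batch 3 used the Zymo kit and all other arrays the Promega kit, so that kit and batch 3 are the same term. One linear model was fitted per gene over all 33 arrays with limma 3.58.1 in R 4.3.3, with terms for the 6 stages and 3 batches (25 residual degrees of freedom) and moderated variances with an intensity trend. Each of the 6 comparisons used limma's moderated test, two-sided, with Benjamini-Hochberg adjustment over the 10986 genes, and a gene was called at an adjusted p under 0.05; "rose" and "fell" are used of genes called in this way. A log2 difference and its SE come from this model and include the batch terms, so they can differ from the difference of the group means. Several comparisons share arrays, so their values are not independent of each other.

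In all, 35 gene lists of mammary, stromal, immune and other cell types and of pathways were written from general knowledge, with 528 of 595 genes matched; some genes stand in more than 1 list. The list for red blood cells had too few measured members and was not tested. Of these, 34 lists had at least 3 measured members and were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 204 tests. At that setting 82 tests passed, 41 up and 41 down, and 1 of them passed with a correlation estimated from the data. Counts "adjusted over the list alone" apply the same adjustment to the members of 1 list.

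Genes named in the comparisons were drawn from those a rule gives: in each comparison, the 8 largest rises and 8 largest falls among called genes whose arrays do not overlap between the groups (or, where none pass, the genes of smallest p), up to 4 members of smallest adjusted p of each list that passed, and a panel of 16 milk, hormone, adipose, matrix and growth factor genes. The model, the comparisons, the gene lists, this rule and all alternatives except those named in the closing section as added later were fixed before the data were examined.

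The procedure was tested on simulated data drawn from the spread of the real arrays, with 200 genes changed by a log2 difference of 0.5, 1 or 2 in each comparison. The genes of the collagen and matrix list were raised by 0.5 as well. Noise was drawn for each gene on its own, so genes did not vary together and no array stood apart in cell content. Recovery was 62.7%, 94% and 97% for day 42 against day 21, 53.7%, 92.5% and 100% for day 63 against day 42, and 56.7%, 80.6% and 93.9% for nulliparous against pubertal glands. It was 38.8%, 86.6% and 97% for lactation against pubertal glands, 29.9%, 80.6% and 98.5% for parous against lactating glands, and 62.7%, 92.5% and 98.5% for parous against nulliparous glands. Between 3.76% and 8.09% of the calls were false.

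The alternatives tried were: no batch term, batch as a random block, no filter or a filter at the 75th percentile, quantile normalization applied again, arrays centred on their median, the mean of a gene's probe sets, every probe set tested, no intensity trend, array weights, a fit of only the groups compared, list means of skeletal muscle, B cells or luminal epithelium as covariates, an adjusted p under 0.01, a 2-fold minimum, single batches, all arrays without batch 3, nulliparous glands as the comparator of lactation, and each array left out in turn. Figures were drawn with matplotlib 3.10.9.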

Results

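Mammary gland RNA from female Sprague-Dawley rats, an outbred laboratory strain, was measured on 33 Affymetrix whole-transcript arrays. The rats were vehicle controls of a study of environmental chemicals and were dosed with olive oil into the stomach. The fifth caudal glands of both sides were taken at 6 stages of gland development. Pre-pubertal glands were collected at postnatal day 21 (n = 10), peri-pubertal glands at day 42 (n = 5) and pubertal glands at day 63 (n = 5). Lactating glands were collected on lactation day 28, at postnatal day 146 (n = 3), and the glands of adult nulliparous and parous rats at day 181 (n = 5 each). The series record gives these numbers as animals, whereas the sample notes give 5 animals per stage. Each array was taken as 1 animal, and if the 10 pre-pubertal arrays came from fewer, their SDs, SEs and p-values are too small. The arrays fell into 3 labelled batches. Batch 1 held arrays of every stage except lactation, batch 2 held the lactation arrays and part of the 3 youngest groups, and batch 3 held 2 nulliparous and 2 parous arrays whose RNA came from another extraction kit. The labels give 1 collection day per stage, so day and stage divide the animals in the same way. The model's p-values rest on the spread between animals within stages, pooled over all 6 stages into 1 estimate per gene. A gene that varies widely in 1 stage therefore has a larger SE in every comparison.

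Of 10986 genes tested, 7239 (65.9%) differed between the stages in limma's moderated F test with batch in the model. Array batch moved many genes as well. Batch 2 differed from batch 1 at 6222 genes with a median absolute log2 difference of 0.269, and batch 3 differed from batch 1 at 8501 genes with a median of 0.751. The first principal component (39.8% of the variance) set the 4 arrays of batch 3 apart from the other 29. On the second component (20%) the lactation arrays lay at the low end and most pre-pubertal arrays at the high end.

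**Figure D1:**
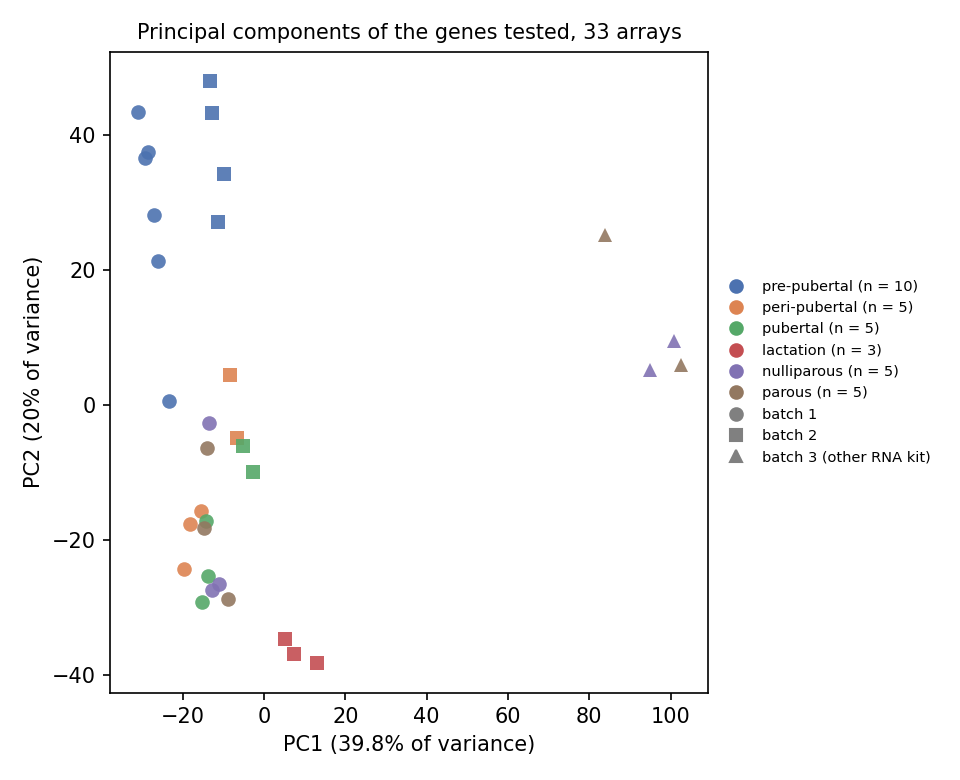
First principal component (horizontal axis, 39.8% of variance) against the second (vertical axis, 20%) of the tested genes; each point is 1 array, coloured by stage and shaped by batch. The 4 triangles of batch 3 lie far to the right of the other 29 arrays, and the 3 lactation arrays lie lowest.

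The first comparison, day 42 with day 21, addressed the onset of puberty. Csn3, which encodes the milk protein kappa-casein, rose 85.7-fold, from a log2 value of 6.37 ± 0.73 (SD, n = 10) to 12.8 ± 0.23 (SD, n = 5), with a log2 difference of 6.42 ± 0.21 (SE) and adjusted p = 1.26e-19. Csn2, which encodes beta-casein, rose 11-fold (log2 difference 3.46 ± 0.52, adjusted p = 1.05e-05), and Pgr, the progesterone receptor, rose 15.4-fold (3.94 ± 0.52, adjusted p = 2.47e-06). Igf2, a fetal growth factor, fell by 2.74 ± 0.24 (6.68-fold, adjusted p = 4.83e-09), and the lipoxygenase gene Alox15 fell by 2.78 ± 0.16 (6.88-fold).

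Of 19 measured luminal epithelium genes, 18 rose and 0 fell at day 42, and 19 rose when adjusted over the list alone (mean log2 difference 1.52, camera adjusted p = 2.48e-12; adjusted p = 0.322 with an estimated correlation). The keratin gene Krt19 rose by 1.77 ± 0.26 and the protease inhibitor gene Spint1 by 1.61 ± 0.22. Hormone-sensing luminal genes had 10 of 12 members up and 1 down, both over all genes and adjusted over the list alone (adjusted p = 2.25e-05; adjusted p = 0.266 with an estimated correlation). Among them were Prlr, the prolactin receptor (2.30 ± 0.22), and the transcription factors Gata3 (1.55 ± 0.21) and Foxa1 (1.47 ± 0.23). Esr1, the estrogen receptor gene, did not pass (0.01 ± 0.15, adjusted p = 0.968). Genes of alveolar and luminal progenitor cells rose at 7 of 11 members, also 7 adjusted over the list alone (adjusted p = 9.19e-05; adjusted p = 0.158 with an estimated correlation), with Elf5 up by 2.06 ± 0.38 and Kit by 1.14 ± 0.19. Basal and myoepithelial genes rose at 7 of 12, again 7 adjusted over the list alone (adjusted p = 0.000719; adjusted p = 0.388 with an estimated correlation). Krt14, a basal keratin, rose by 2.14 ± 0.30 and Oxtr, the oxytocin receptor, by 1.84 ± 0.23.

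Milk protein genes rose at 12 of 17 members and fell at 2, with the same counts adjusted over the list alone (adjusted p = 7.89e-06; adjusted p = 0.147 with an estimated correlation). Besides the caseins, the mucin gene Muc15 rose by 2.69 ± 0.37 and Muc1 by 2 ± 0.18, while Wap, the whey acidic protein gene, did not pass (0.76 ± 0.56, adjusted p = 0.32). Lalba, which encodes alpha-lactalbumin, had a log2 difference of 1.37 ± 0.46 (adjusted p = 0.0224). That call was lost without peri-pubertal array 1 (adjusted p = 0.0604) or 3 (adjusted p = 0.0575). With the luminal list mean as a covariate, the Lalba difference was -1.08. Olah, a thioesterase that ends fatty acid chains early in milk fat synthesis, rose 16.1-fold (4.01 ± 0.33), and the water channel gene Aqp5 rose by 3.30 ± 0.45. Genes of endoplasmic reticulum folding and secretion rose at 14 of 20 members and at 15 adjusted over the list alone (adjusted p = 1.01e-05; adjusted p = 0.388 with an estimated correlation), among them Xbp1 (0.81 ± 0.12). Involution and remodelling genes rose at 15 of 20 and fell at 1, with 16 up adjusted over the list alone (adjusted p = 3.44e-07; adjusted p = 0.147 with an estimated correlation). Its members Lbp (1.92 ± 0.23), a binding protein for bacterial lipopolysaccharide, Tgfb3 (1.5 ± 0.19), a growth factor, and Mmp14 (1.14 ± 0.14), a membrane protease, were up. Mki67, a marker of dividing cells, did not pass (-0.08 ± 0.48, adjusted p = 0.922).

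White adipocyte genes fell at 16 of 20 members and rose at 0 (mean -0.74, adjusted p = 6.9e-10; adjusted p = 0.266 with an estimated correlation), and 17 fell when adjusted over the list alone. The adipocyte regulator Pparg fell by 1.16 ± 0.16, the glucose transporter gene Slc2a4 by 1.06 ± 0.15 and the leptin gene Lep by 1.61 ± 0.32. Imprinted genes of perinatal growth fell at 3 of 7 members, also 3 adjusted over the list alone (adjusted p = 0.00743; adjusted p = 0.337 with an estimated correlation): Igf2, Nnat (fell by 2.12 ± 0.22) and Plagl1 (fell by 0.70 ± 0.17). Igfbp3, which binds insulin-like growth factors, fell by 2.10 ± 0.24. Lymphocyte genes had lower values at day 42. T cell genes fell at 14 of 15 members (mean -1.99, adjusted p = 3.38e-07; adjusted p = 0.51 with an estimated correlation) and B cell genes at 11 of 11 (mean -1.75, adjusted p = 0.000416; adjusted p = 0.605 with an estimated correlation), with the same counts adjusted over the list alone. The T cell receptor component Cd3g fell by 3.44 ± 0.67, and the lymph node chemokine gene Ccl19 by 2.98 ± 0.76. The B cell list mean ranged from 6.57 to 9.84 over the 10 pre-pubertal arrays, and the skeletal muscle list mean stood at 10.09 in pre-pubertal array 10, 9.64 in peri-pubertal array 1 and 9.21 in peri-pubertal array 4, against 6.53 to 8.21 in the other arrays of both groups.

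In all, 3552 genes were called at day 42 against day 21, 1883 up and 1669 down (290 and 322 of them at least 2-fold). There were 550 genes (5.01%) that did not overlap between the groups, where chance gives 0.0666%, and 548 of them were called. Overlap, here and below, was read from values not corrected for batch. The share by chance takes arrays as alike apart from stage, so batch can move these counts. Within batch 1, 2457 genes were called, of which 2293 were shared with all arrays. Within batch 2, 643 were called, of which 639 were shared. With the luminal list mean as a covariate 310 genes were called, and with the B cell list mean 1987.

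**Figure D2:**
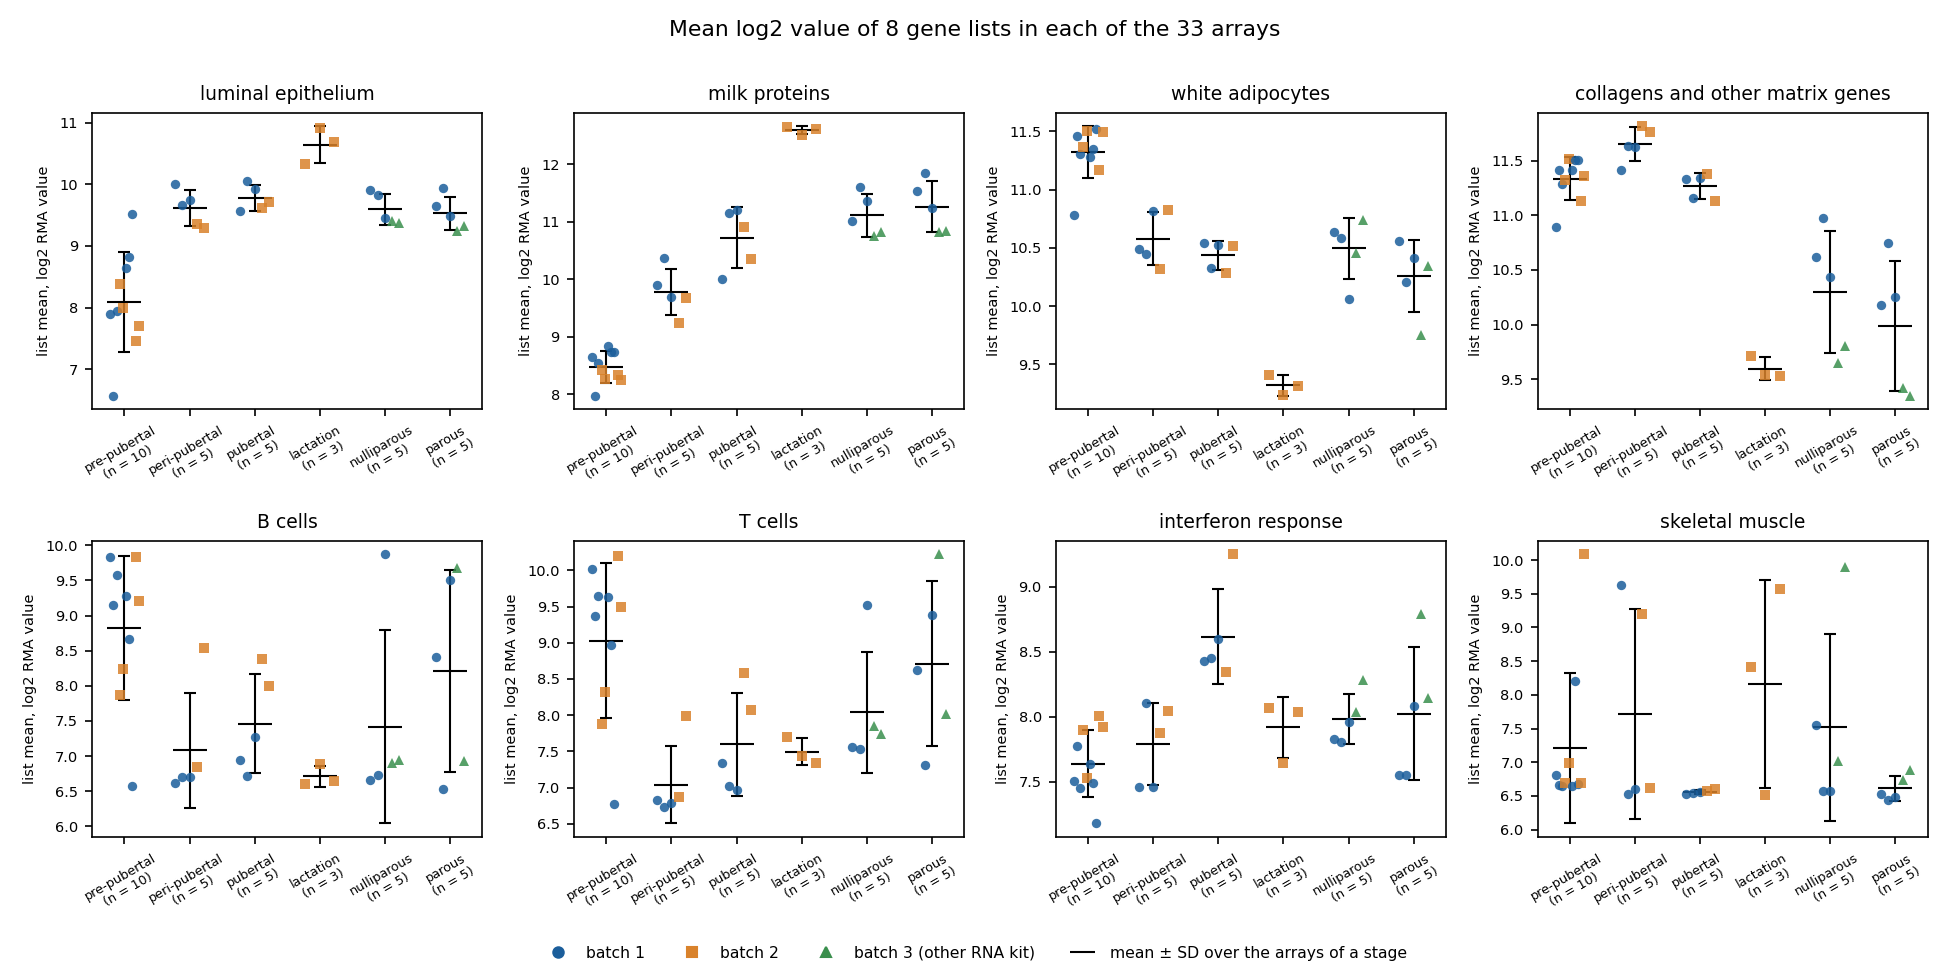
Mean log2 value of 8 gene lists (vertical axes) in each array, by stage (horizontal axis), with bars for the mean ± SD of a stage and marker shape for batch. Luminal epithelium means rose from 8.09 to 9.61 between the 2 youngest stages, and white adipocyte means were lowest in lactation (9.32).

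The second comparison, day 63 with day 42, followed later puberty. Milk protein genes were higher at day 63, with 4 of 17 members up over all genes and 9 adjusted over the list alone (mean 0.95, adjusted p = 3.27e-10). This was the only 1 of the called lists that passed with an estimated correlation (adjusted p = 0.036). Wap rose 6.87-fold (2.78 ± 0.64, adjusted p = 0.0243), from 3 of the 5 pubertal arrays (10.40, 11.75 and 12.22), while the other 2 (7.62 and 7.66) lay within the peri-pubertal range of 6.44 to 7.81. Csn2 rose 5.45-fold (2.45 ± 0.60, adjusted p = 0.0328), from pubertal arrays at 12.68, 12.86 and 12.89. The other pubertal arrays (8.70 and 11.125) lay within the peri-pubertal Csn2 range of 8.41 to 11.17. Xdh, an enzyme of milk fat droplet secretion, rose by 0.80 ± 0.13 (adjusted p = 0.00285). Interferon response genes rose at 8 of 18 members, and 17 rose when adjusted over the list alone (mean 0.82, adjusted p = 4.54e-20; adjusted p = 0.133 with an estimated correlation). Among them were Irf9 (0.61 ± 0.11), Irf7 (0.99 ± 0.22) and Ifit1 (1.12 ± 0.25). Of the immune cell lists, T cells (mean 0.55, adjusted p = 0.0214; adjusted p = 0.801 with an estimated correlation) and macrophages (mean 0.21, adjusted p = 0.0205; adjusted p = 0.718 with an estimated correlation) were higher, with 0 members called in either. The T cell test was lost without peri-pubertal array 1 (adjusted p = 0.059) or pubertal array 4 (0.224), and the macrophage test without peri-pubertal array 1 (0.0964) or pubertal array 1 (0.435). With only arrays of batch 2 the macrophage mean was -0.038. Mast cell genes were lower, with 1 of 7 members down and 2 adjusted over the list alone (mean -0.39, adjusted p = 0.00829; adjusted p = 0.517 with an estimated correlation). Collagen and other matrix genes fell at 5 of 24 members and at 10 adjusted over the list alone (mean -0.38, adjusted p = 2.75e-10; adjusted p = 0.266 with an estimated correlation), led by Eln, the elastin gene, which fell by 0.81 ± 0.14.

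Sterol synthesis genes fell at 2 of 14 members and at 6 adjusted over the list alone (adjusted p = 3.98e-05; adjusted p = 0.266 with an estimated correlation), among them Sqle, the squalene epoxidase gene (fell by 0.76 ± 0.19). Endoplasmic reticulum folding genes fell at 3 of 20 and at 9 adjusted over the list alone (adjusted p = 2.27e-08; adjusted p = 0.266 with an estimated correlation), with the chaperone gene Hspa5 down by 0.51 ± 0.12. Pcsk2, a prohormone convertase gene, rose 4.25-fold (2.09 ± 0.20, adjusted p = 1.92e-07). Cyp24a1, which degrades vitamin D, rose by 1.86 ± 0.30 and the eosinophil chemokine gene Ccl11 by 1.79 ± 0.26. Penk, the proenkephalin gene, fell by 1.52 ± 0.29 and Alox15 by 1.32 ± 0.19. Pgr (-0.88 ± 0.61), Areg (-0.86 ± 0.48) and Mki67 (-0.43 ± 0.56) did not pass. The skeletal muscle list mean lay between 6.53 and 6.61 in the 5 pubertal arrays and at 9.64 and 9.21 in peri-pubertal arrays 1 and 4 (mean difference -1.16, 0 of 14 members called).

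At day 63 against day 42, 134 genes were called, 79 up and 55 down, and 1627 had an unadjusted p under 0.05. There were 248 genes (2.26%) that did not overlap, where chance gives 0.794%, and 49 of them were called. Within batch 1 (3 arrays each) limma called 1 gene and within batch 2 (2 each) 0 (693 at an unadjusted p under 0.05), and 5 genes were called with no batch term. The count moved to 421 without peri-pubertal array 1, 74 without 2, 52 without 3, 87 without 4 and 16 without 5, and to 41, 24 and 77 without pubertal arrays 2, 3 and 5. Pcsk2, Cyp24a1, Ccl11, Alox15, Xdh, Eln and Irf9 were called with each of the 10 arrays left out in turn. Without peri-pubertal array 5, Wap (adjusted p = 0.0914), Csn2 (0.0968), Ifit1 (0.0628), Sqle (0.0848), Hspa5 (0.129) and Penk (0.0542) were not called, nor was Irf7 without peri-pubertal array 3 (0.059).

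The third comparison, nulliparous glands of day 181 with pubertal glands of day 63, addressed virgin adulthood. Collagen and other matrix genes were lower in the adults, with 12 of 24 members down over all genes and 15 adjusted over the list alone (mean -0.56, adjusted p = 8.04e-13; adjusted p = 0.266 with an estimated correlation). Lox, which cross-links collagen and elastin, fell 4.12-fold (log2 difference -2.04 ± 0.23, adjusted p = 2.12e-06), Eln fell by 1.35 ± 0.16, Col3a1 by 0.98 ± 0.18 and Col1a1 by 0.87 ± 0.20. Interferon response genes fell at 9 of 18 members and at 14 adjusted over the list alone (mean -0.71, adjusted p = 5.34e-10; adjusted p = 0.266 with an estimated correlation), with Rsad2 down by 1.26 ± 0.23. Both this comparison and the preceding one use the same 5 pubertal arrays.

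Clock genes moved in both directions, 5 of 14 up and 2 down, with 6 up and 2 down adjusted over the list alone (mean 0.19, adjusted p = 0.0142; adjusted p = 0.266 with an estimated correlation). Per2, a repressor of the clock, rose 3.78-fold (1.92 ± 0.16, adjusted p = 5.92e-09) and Cry1 by 1.01 ± 0.15, while the activators Npas2 and Bmal1 fell by 2 ± 0.18 and 1.32 ± 0.19. The clock list test was lost without nulliparous array 1 (adjusted p = 0.0548), and the list mean was -0.205 with no batch term. Immediate early and heat shock genes rose at 2 of 15 members and at 8 adjusted over the list alone (adjusted p = 5.65e-06; adjusted p = 0.266 with an estimated correlation), with the chaperone gene Hsph1 up by 1.37 ± 0.22. Endoplasmic reticulum folding genes rose at 7 of 20 and at 9 adjusted over the list alone (adjusted p = 3.87e-08; adjusted p = 0.266 with an estimated correlation), among them Herpud1 (0.59 ± 0.10) and Sdf2l1 (0.99 ± 0.21).

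Milk protein genes rose at 3 of 17 members, also 3 adjusted over the list alone (adjusted p = 0.000287; adjusted p = 0.266 with an estimated correlation). Lpo, the lactoperoxidase gene, was up by 1.05 ± 0.19, while Csn2 (0.54 ± 0.67, adjusted p = 0.753) and Wap (0.37 ± 0.72, adjusted p = 0.85) did not pass. The fatty acid binding protein gene Fabp3 rose 5.91-fold (2.56 ± 0.39). Abcg2, a transporter that moves riboflavin into milk, rose by 1.36 ± 0.26. Scd, a fatty acid desaturase gene, fell 5.16-fold (-2.37 ± 0.55, adjusted p = 0.0113), a call lost without nulliparous array 3 (adjusted p = 0.0709). Among markers of other tissues, the T cell list mean stood at 9.52 in nulliparous array 3 against 7.53 to 7.85 in the other 4, and the muscle list at 9.90 in nulliparous array 5.

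Between adult virgins and pubertal glands 469 genes were called, 206 up and 263 down. There were 769 genes (7%) that did not overlap, where chance gives 0.794%, and 210 of them were called. Within batch 1, the only batch that holds both groups, 250 genes were called and 194 of them were shared with all arrays; without batch 3 the count was 348. It was 293 without pubertal array 2, 204 without pubertal array 3, 240 without nulliparous array 2 and 262 without nulliparous array 3.

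The fourth comparison set lactating glands against pubertal glands, the oldest virgin glands that share a batch with them. The former were of day 146 and the latter of day 63, so age differs along with lactation. Csn1s2b, an alpha-s2-casein gene, rose 105-fold, from 7.38 ± 0.17 (SD, n = 5) to 13.94 ± 0.06 (SD, n = 3), with a log2 difference of 6.71 ± 0.19 and adjusted p = 2.17e-21. Wap rose 19.7-fold (4.30 ± 0.79, adjusted p = 8.63e-05), Lpo 24.7-fold (4.62 ± 0.21) and Pigr, which carries immunoglobulin A into milk, 31.4-fold (4.97 ± 0.29). Col1a1, a chain of type I collagen, fell 7.75-fold (-2.95 ± 0.22, adjusted p = 3.4e-11).

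Milk protein genes rose at 9 of 17 members and fell at 0, with the same counts adjusted over the list alone (mean 2.05, adjusted p = 1.25e-05; adjusted p = 0.147 with an estimated correlation). Csn2 had a log2 difference of 1.99 ± 0.74 (adjusted p = 0.0314), not called without pubertal array 5 (0.062) or lactation array 1 (0.0535), 2 (0.0895) or 3 (0.0642), and Lalba did not pass (0.99 ± 0.65, adjusted p = 0.24). Within batch 2 Lalba stood at 13.69 in lactating and 12.77 in pubertal glands, near the top of the scale, where saturation can compress differences. Its arrays did not overlap between the 2 groups. Its SE is pooled over all stages, among them pre-pubertal arrays at 7.47 to 12.94. Nutrient transport and lactose genes rose at 8 of 13 members, also 8 adjusted over the list alone (adjusted p = 0.000284; adjusted p = 0.266 with an estimated correlation). Abcg2 rose 8.15-fold (3.03 ± 0.28), the folate receptor gene Folr1 by 2.69 ± 0.22 and the metal transporter gene Slc39a8 by 1.86 ± 0.15. Sterol synthesis genes rose at 9 of 14 and at 10 adjusted over the list alone (adjusted p = 0.000322; adjusted p = 0.327 with an estimated correlation), with Sqle up by 1.59 ± 0.23 and Nsdhl by 1.17 ± 0.15. Luminal epithelium genes rose at 9 of 19 and at 11 adjusted over the list alone (adjusted p = 0.00387; adjusted p = 0.787 with an estimated correlation), among them the keratin genes Krt7 (2.68 ± 0.41) and Krt8 (1.91 ± 0.38). Other large rises were in Il1rn, the interleukin-1 receptor antagonist (4.82 ± 0.39), Ceacam4 (5.86 ± 0.26) and the opiorphin precursor gene Oprpn (5.13 ± 0.64).

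Collagen and matrix genes fell at 23 of 24 members, also 23 adjusted over the list alone (mean -1.70, adjusted p = 3.74e-22; adjusted p = 0.133 with an estimated correlation), and Sparc fell by 1.49 ± 0.09. This list was lower in nulliparous than in pubertal glands too (12 of 24 members down, mean -0.56), so part of the fall may go with age. Lists were not tested for lactating against nulliparous glands. Fibroblast genes fell at 13 of 14, again 13 adjusted over the list alone (mean -1.29, adjusted p = 2.18e-09; adjusted p = 0.158 with an estimated correlation). Pcolce, an enhancer of procollagen processing, fell by 1.81 ± 0.21 and dermatopontin, Dpt, by 1.30 ± 0.13. White adipocyte genes fell at 17 of 20 and at 19 adjusted over the list alone (mean -1.14, adjusted p = 2.74e-10; adjusted p = 0.266 with an estimated correlation), with adiponectin, Adipoq, down by 1.79 ± 0.18 and Plin1, which coats lipid droplets, by 1.81 ± 0.23. Hormone-sensing luminal genes fell at 6 of 12 and at 7 adjusted over the list alone (adjusted p = 0.000585; adjusted p = 0.322 with an estimated correlation), among them Foxa1 (fell by 1.75 ± 0.33) and Prlr (fell by 1.43 ± 0.31). Pgr did not pass (-1.80 ± 0.75, adjusted p = 0.0544).

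Fatty acid and triglyceride synthesis genes fell at 7 of 18 members and rose at 1, with 8 down adjusted over the list alone (adjusted p = 0.0215; adjusted p = 0.695 with an estimated correlation). The list test was lost without lactation array 2 (adjusted p = 0.128). White adipocyte genes fell as well, at 17 of 20 members. Whole-gland RNA cannot tell a lower share of fat cells from lower expression within cells. The list gene Fasn was not matched to a probe set with 1 symbol. Dgat2, an enzyme of triglyceride synthesis, fell by 2.01 ± 0.21 and Scd2 by 1.81 ± 0.18. Imprinted genes fell at 5 of 7, also 5 adjusted over the list alone (adjusted p = 0.00101; adjusted p = 0.266 with an estimated correlation), among them Plagl1 (fell by 2.24 ± 0.24). Igf1, the insulin-like growth factor gene, fell by 1.28 ± 0.16 and Ghr, the growth hormone receptor, by 1.17 ± 0.27. Interferon response genes fell at 12 of 18 and at 14 adjusted over the list alone (adjusted p = 2.75e-05; adjusted p = 0.437 with an estimated correlation), against the same pubertal arrays in which they had risen. Their member Ifi44 fell by 1.24 ± 0.20. The skeletal muscle list mean was 8.41 in lactation array 1 and 9.56 in lactation array 3, against 6.51 in array 2 and 6.53 to 6.61 in the pubertal arrays.

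Lactating glands differed from pubertal glands at 4472 genes, 2611 up and 1861 down (58.4% up, and 48.6% when each array was centred on its median). At least 2-fold apart were 317 up and 580 down, and with no batch term 725 were up and 1055 down, so the balance of rises and falls depended on the setting. There were 3939 genes (35.9%) that did not overlap, where chance gives 3.57%, and 3003 of them were called. Within batch 2, which holds 3 lactation and 2 pubertal arrays, 2383 genes were called and 2322 of them were shared with all arrays. With nulliparous glands in place of pubertal ones, 12 of 72 called gene values were not called, among them Mx2 (-0.77), Prlr (-0.81), Ifi44 (-0.58) and Csn2 (1.45).

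**Figure D3:**
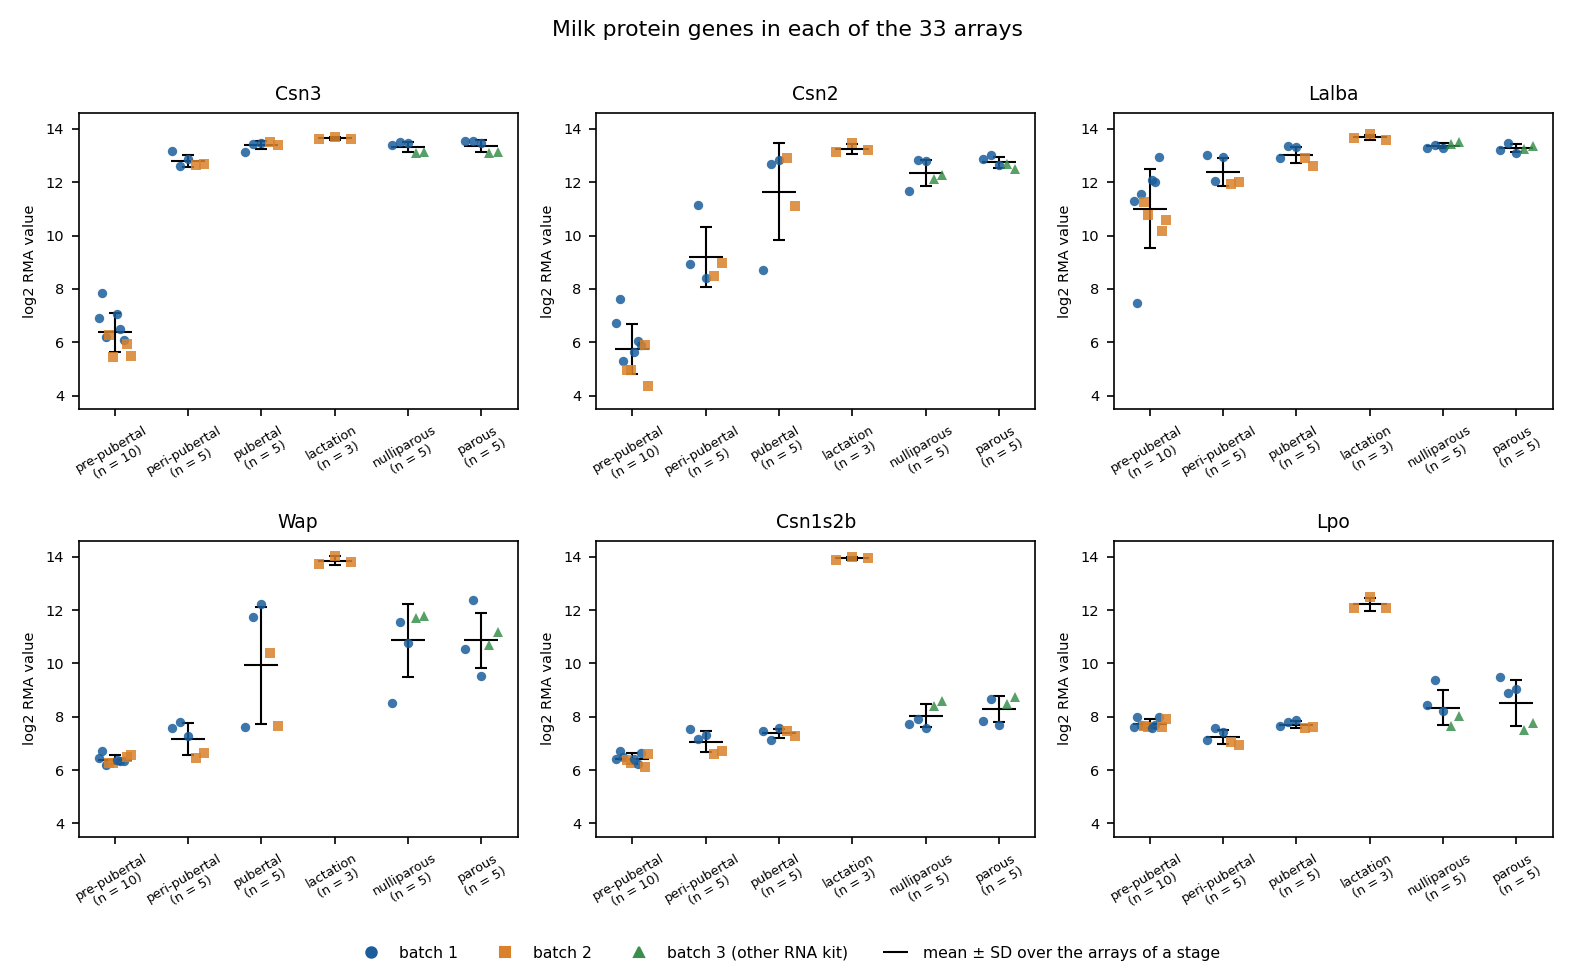
Log2 value of 6 milk protein genes (vertical axes) in each array, by stage (horizontal axis), with bars for the mean ± SD of a stage and marker shape for batch. Csn3 was near 12.8 by day 42, whereas Csn1s2b reached 13.94 in lactation against 7.38 at day 63.

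The fifth comparison set parous glands of day 181 against glands at the end of lactation, to describe the gland after weaning. Csn1s2b fell 71.5-fold (log2 difference -6.16 ± 0.21), Wap 15.3-fold (-3.94 ± 0.91, adjusted p = 0.00147), Lpo by 3.39 ± 0.24 and Pigr by 2.97 ± 0.33. Sncg, the gamma-synuclein gene, rose 9.27-fold (3.21 ± 0.29), and Rbp4, which carries retinol, rose by 2.62 ± 0.28. Csn2 (-1.04 ± 0.85, adjusted p = 0.358) and Lalba (-0.99 ± 0.75, adjusted p = 0.323) did not pass. Csn2 lay at 13.12 to 13.48 in lactating and 12.50 to 13.02 in parous arrays. Lalba lay at 13.58 to 13.79 and 13.09 to 13.48. The highest value in the table is 14.228, so saturation can have compressed these differences. The arrays of the 2 groups did not overlap in either gene. The SEs are pooled over all stages, and some other stages varied more. Lalba lay at 7.47 to 12.94 in pre-pubertal arrays and Csn2 at 8.70 to 12.89 in pubertal arrays.

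Milk protein genes fell at 6 of 17 members, with 7 down and 1 up adjusted over the list alone (adjusted p = 0.00264; adjusted p = 0.266 with an estimated correlation). Transport and lactose genes fell at 8 of 13 and at 9 adjusted over the list alone (adjusted p = 0.00182; adjusted p = 0.266 with an estimated correlation), with Abcg2 down by 2.23 ± 0.33 and Slc39a8 by 1.82 ± 0.17. Sterol synthesis genes fell at 10 of 14, also 10 adjusted over the list alone (adjusted p = 0.000322; adjusted p = 0.327 with an estimated correlation), among them Nsdhl (fell by 1.44 ± 0.18). Luminal epithelium genes fell at 10 of 19 and at 11 adjusted over the list alone (adjusted p = 0.00101; adjusted p = 0.736 with an estimated correlation), with Krt7 down by 3.32 ± 0.47 and Krt8 by 2.42 ± 0.44. Hormone-sensing luminal genes rose at 5 of 12 and at 9 adjusted over the list alone (adjusted p = 0.00107; adjusted p = 0.337 with an estimated correlation). Areg, an epidermal growth factor receptor ligand, was up by 2.44 ± 0.68 and Prom1 by 1.89 ± 0.39.

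White adipocyte genes rose at 14 of 20 members, with 16 up and 1 down adjusted over the list alone (mean 1.00, adjusted p = 5.14e-09; adjusted p = 0.322 with an estimated correlation). Adipoq rose by 1.49 ± 0.21 and adipsin, Cfd, by 1.81 ± 0.26. Fatty acid and triglyceride synthesis genes rose at 6 of 18 and fell at 1, with the same counts adjusted over the list alone (adjusted p = 0.00406; adjusted p = 0.575 with an estimated correlation). Scd2 rose by 2.02 ± 0.21 and the lipid regulator gene Srebf1 by 1.71 ± 0.26. As white adipocyte genes rose too, a change in the share of fat cells cannot be told apart from a change within cells. Collagen and matrix genes rose at 17 of 24 and fell at 1, again the same adjusted over the list alone (mean 0.84, adjusted p = 6.63e-10; adjusted p = 0.266 with an estimated correlation), with Fn1, the fibronectin gene, up by 1.51 ± 0.23 and Col1a1 by 1.5 ± 0.25. Fibroblast genes rose at 10 of 14, also 10 adjusted over the list alone (adjusted p = 4.33e-06; adjusted p = 0.266 with an estimated correlation), among them Gsn (1.31 ± 0.19). Igf1 rose by 1.05 ± 0.18.

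Lymphocyte genes differed as well. B cell genes rose at 3 of 11 members and at 8 adjusted over the list alone (mean 2.17, adjusted p = 0.00253; adjusted p = 0.692 with an estimated correlation), and T cell genes at 1 of 15 and 0 adjusted over the list alone (mean 1.58, adjusted p = 0.00254; adjusted p = 0.758 with an estimated correlation). With the B cell list mean as a covariate the T cell list difference was -0.20. Cr2, a complement receptor of B cells, was up by 4.10 ± 1.35 (adjusted p = 0.0197), not called without parous array 3 (0.0636), with both group means (7.54 and 5.06) below the floor of 7.645. The B cell list mean was 8.41, 9.51 and 9.67 in parous arrays 1, 3 and 4, against 6.53 and 6.93 in arrays 2 and 5 and 6.6 to 6.89 in the lactation arrays. The skeletal muscle list mean was 8.41 and 9.56 in lactation arrays 1 and 3 and at most 6.88 in the parous arrays.

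After weaning 3610 genes were called, 1334 up and 2276 down (37% up, and 48.2% when each array was centred on its median). At least 2-fold apart were 435 up and 355 down. A fit of only the groups compared called 2141 up and 2112 down, with 2252 genes shared with all arrays, and a fit with no batch term called 3001 genes, with 1740 shared. There were 3055 genes (27.8%) that did not overlap, where chance gives 3.57%, and 1598 of them were called. No batch holds both groups, so batch alone can separate genes and the 3.57% is no fair measure. The contrast itself rests on batch terms estimated from the other stages. Without batch 3, 3591 genes were called.

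The sixth comparison set parous against nulliparous glands of the same age, day 181, to ask what differs with pregnancy history. Across 10986 genes, 2 were called. Mcpt8l2, a mast cell protease gene, rose 1.60-fold (0.68 ± 0.12, adjusted p = 0.0377), and Pcdh17, a protocadherin gene, fell 2.27-fold (-1.18 ± 0.21, adjusted p = 0.036). Both folds are approximate, since the batch 1 means of Mcpt8l2 (7.30 parous, 6.73 nulliparous) and the parous mean of Pcdh17 (6.62) lay below the floor of 7.645. Csn2 (0.40 ± 0.60, adjusted p = 0.91), Wap (-0.01 ± 0.64, adjusted p = 0.998), Pigr (0.98 ± 0.24, adjusted p = 0.259), Postn (-0.53 ± 0.13, adjusted p = 0.32), Col1a1 (-0.58 ± 0.18, adjusted p = 0.514), Esr1 (-0.31 ± 0.17, adjusted p = 0.842) and Pgr (-0.16 ± 0.61, adjusted p = 0.968) did not pass.

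Camera called 9 lists, with 0 members called over all genes in each. Collagen and matrix genes were lower in parous glands, 7 of 24 down adjusted over the list alone (mean -0.30, adjusted p = 2.74e-10; adjusted p = 0.266 with an estimated correlation), and imprinted genes were lower with 0 of 7 (mean -0.34, adjusted p = 0.00197; adjusted p = 0.266 with an estimated correlation). Plasma cell genes were higher, 5 of 9 up adjusted over the list alone (mean 0.49, adjusted p = 0.000425; adjusted p = 0.266 with an estimated correlation), with Mzb1 at 1.12 ± 0.46 (adjusted p = 0.711). B cell genes (mean 0.79, adjusted p = 0.00136; adjusted p = 0.652 with an estimated correlation) and T cell genes (mean 0.67, adjusted p = 0.000298; adjusted p = 0.652 with an estimated correlation) were also higher, with 0 members adjusted over the list alone in either. The difference for the list of B cells, parous against nulliparous, was 0.395 with only arrays of batch 1 (adjusted p = 0.197) and 1.385 with only arrays of batch 3 (adjusted p = 1.42e-05). The B cell list test was lost without nulliparous array 1 (adjusted p = 0.0708) or parous array 3 (0.0691) or 4 (0.173), and the T cell test without parous array 4 (0.137). The list of T cells, parous against nulliparous, differed by 0.24 with only arrays of batch 1 (adjusted p = 0.249) and by 1.321 with only arrays of batch 3. Cell cycle genes were higher in parous glands (mean 0.32, adjusted p = 0.000951; adjusted p = 0.791 with an estimated correlation) and fibroblast genes lower (mean -0.21, adjusted p = 0.00505; adjusted p = 0.517 with an estimated correlation), with 0 members of either adjusted over the list alone. The cell cycle test was lost without parous array 2 (mean 0.02, adjusted p = 0.698) or nulliparous array 1 (0.18), and the fibroblast test without nulliparous array 2 (0.136). With only arrays of batch 1 the imprinted list (adjusted p = 0.0523) and the fibroblast list (adjusted p = 0.0545) did not pass. Skeletal muscle genes were lower in parous glands (mean -0.91, adjusted p = 0.000322; adjusted p = 0.64 with an estimated correlation), which did not pass without nulliparous array 5 (adjusted p = 0.211). White adipocyte genes were lower (mean -0.24, adjusted p = 0.000226; adjusted p = 0.553 with an estimated correlation), which did not pass without parous array 4 (adjusted p = 0.287). With only arrays of batch 1 the means were -0.414 for skeletal muscle (adjusted p = 0.116) and -0.035 for white adipocytes (adjusted p = 0.951), and with only arrays of batch 3 they were -1.649 and -0.546.

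At an unadjusted p under 0.05 there were 668 genes, and 19 genes (0.173%) did not overlap, where chance gives 0.794%. Limma called 0 genes within batch 1 (435 at an unadjusted p under 0.05), 0 within batch 3 (308) and 0 without batch 3 (354). The count was 1 without nulliparous array 1, 0 without nulliparous arrays 2, 4 or 5, 8 without nulliparous array 3, 0 without parous arrays 1, 3 or 4, and 4 without parous array 2. Where it was 0, between 414 and 639 genes had an unadjusted p under 0.05. In simulated data at this size, 62.7% of genes changed by 0.5 on the log2 scale, 92.5% of those changed by 1 and 98.5% of those changed by 2 were recovered. The simulated noise was independent between genes and held no arrays that differed in cell content. These rates therefore do not give the power in the real arrays.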

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

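All tests of explanations in this part were chosen after the results were seen; the counts over other splits of the arrays were planned, except those for the stage-specific genes in the other observations. Within groups of 5 or 10 arrays, 12 of 170 list values (7.06%) and 49 of 785 gene values (6.24%) held 1 array far from the others by Dixon's ratio, where chance flags about 1 in 20.

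Nulliparous array 3 stood above the other 4 in B cells (9.88; others 6.66 to 6.94), T cells (9.52), lymph node stroma (9.90) and MHC class II (10.05), and in B3gnt5 (10.09), Ccl19 (9.85), Cr2 (10.31), Il22ra2 (10.17), Lef1 (10.13) and Slc7a11 (8.31). Peri-pubertal array 5 stood above its group in B cells (8.54; others 6.61 to 6.84), T cells (7.99), B3gnt5 (9.14), Ccl19 (8.03), Cd3g (8.24), Ciita (7.65), Cr2 (8.39), Il22ra2 (8.81) and Slc7a11 (6.51), and below it in Esr1 (8.72). Pre-pubertal array 8 lay below the other 9 in B3gnt5 (5.97), Cr2 (5.28) and Il22ra2 (5.55), and above them in Areg (8.56) and Oprpn (8.91).

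Pre-pubertal array 2 lay below its group in Btn1a1 (5.88), Elf5 (5.80), Lalba (7.47), Muc15 (5.11), Plet1 (5.43) and Prr27 (7.47). Pre-pubertal array 1 lay below in white adipocytes (10.79), mast cells (7.10), Adipoq (12.63) and Igf1 (11.63). Pre-pubertal array 10 lay above in skeletal muscle (10.09) and Ocm (6.86), array 4 above in Pcdh17 (8.92) and below in Sdf2l1 (6.49), and array 9 below in Npas2 (8.28). Peri-pubertal array 2 lay above in imprinted genes (8.86), Csn2 (11.17), Plagl1 (10.56) and Sqle (8.82), and below in Plet1 (9.78) and Clca5 (8.49). Other peri-pubertal values were Fn1 in array 1 (12.74, low), Igf1 in array 3 (12.38, high) and Lox in array 4 (11.80, high). Pubertal array 1 lay above in immediate early genes (9.04) and Areg (8.91), and below in Csn3 (13.12) and Tll1 (9.20); Elapor1 was low in array 4 (9.76). Pubertal array 5 lay above in interferon response (9.25), Ifit1 (9.65), Pigr (8.78) and RT1-S3 (11.02). Fabp3 was low in nulliparous array 1 (10.07), and Lao1 (8.73) and Postn (12.87) were high in parous array 2.

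Lymphocyte genes were lower in peri-pubertal than in pre-pubertal glands. A difference between batches was excluded as the whole of it, since the smallest fall of the B and T cell lists within a batch was -1.095. A lower share of all non-epithelial tissue was excluded as well: T cell minus fibroblast list means differed by -2.15 (exact permutation p = 0.00333). Lymph node tissue in some samples stays open, and the values it needs were there: over the 10 pre-pubertal arrays the B cell mean followed the node chemokines Ccl19, Ccl21 and Cxcl13 (Pearson's r = 0.915, permutation p = 5e-04; 0.739 without the 2 farthest arrays). A change in lymphocytes of the gland with age was not tested.

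Interferon response genes were higher in the pubertal group than in the peri-pubertal group. The smallest difference with 1 pubertal array left out was 0.701, which excluded 1 animal as the whole of it. Within batches the smaller difference was 0.817, so batch did not account for it. With the B cell list mean as a covariate the difference was 0.781, so B cell content did not account for it either. The B cell list was itself not called in this comparison (camera adjusted p = 0.265). The T cell and macrophage lists, which were called, were not used as covariates, so a part for these cells was not tested. A shared day or exposure of that group was not tested and stays open, as does age.

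Clock genes were shifted in nulliparous against pubertal glands. All 7 called clock genes stayed called the same way without the batch 3 arrays and their extraction kit, which excluded these as the whole of it. The mean difference was 0.77 over 8 genes (Per, Cry, Dbp, Tef and Nr1d1) and -1.12 over Bmal1, Npas2 and Clock, a gap of 1.89, with Nr1d1 at -0.40. In other comparisons Npas2 and Per2 differed by 1.58 and -0.98 (peri-pubertal against pre-pubertal), 0.29 (not called) and -0.78 (lactation against pubertal) and -2.14 and 2.58 (parous against lactation), so they did not move in 1 direction with age. Time of day of sacrifice stays open, because the labels give none and each stage was collected on 1 day.

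The count of genes called was set against other splits of the same arrays. For peri-pubertal against pre-pubertal, 1 of 100 splits (the real one) gave as many as 3552 genes (highest other 2894), for pubertal against peri-pubertal 3 of 100 gave as many as 134 (highest other 205), and for nulliparous against pubertal 1 of 100 gave 469 (highest other 2). For lactation against pubertal 1 of 56 gave 4472 (highest other 1107) and for parous against lactation 1 of 56 gave 3610. In the latter, the highest other, 1786, put the lactation arrays with parous arrays 4 and 5 against batch 1. For peri-pubertal against pre-pubertal, no other split reached the real count. Chance was excluded there, with no adjustment over the comparisons. No other split reached the real count for nulliparous against pubertal either. The same held for the 2 comparisons with lactation, where 1 of 56 is the lowest share possible. The splits exchanged arrays across batches. Nulliparous and pubertal glands share only batch 1, lactating and pubertal glands only batch 2, and parous and lactating glands no batch. In these comparisons the splits cannot tell stage from batch and do not decide whether chance gave the counts. For pubertal against peri-pubertal, other splits reached the real count, which ran from 16 to 421 with 1 array left out. Chance was not clearly excluded there. For parous against nulliparous, 5 of 100 gave at least 2 genes and chance was not excluded. The highest other, 440, put nulliparous arrays 1 and 3 with parous arrays 1, 3 and 4, and all 4 lymphocyte-high adult arrays were on that side, which points to a structure of the samples. In the test of any stage 1 of 100 gave 7239 (highest other 422), and for batch 2 against batch 1, 1 of 100 gave 6222 (highest other 0), so chance was excluded. For batch 3 against batch 1, 1 of 100 gave 8501, with chance excluded; the highest other, 7957, came from a draw that kept the same 4 arrays in batch 3.

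For the number of lists passing within a comparison, chance was not excluded in any. In the order of the 6 comparisons, 5 of 100 splits gave as many as 20 lists (highest other 21), 11 of 100 as many as 15 (18), and 42 of 100 as many as 11 (17). The others were 16 of 56 for 14 (22), 10 of 56 for 13 (18) and 46 of 100 for 9 (17).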

How the results depend on the processing

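Each count of genes was recomputed under the alternatives listed with the methods; adding the B cell and skeletal muscle list means together as covariates, leaving batch 3 out of the comparisons of the 3 youngest groups and of lactation, and the settings for the stage-specific counts were chosen after seeing the data. The test of any of the 6 stages gave 4829 genes (luminal covariate) to 10005 (every probe set), and for the batch counts only the fit with no filter was tried (7660 for batch 2 and 10967 for batch 3). Without a batch term, calls were 1325 for peri-pubertal against pre-pubertal, 5 for pubertal against peri-pubertal, 1780 for lactation against pubertal and 1 for parous against nulliparous; with batch as a random block the last was 1. With array weights, 1653 genes were called for pubertal against peri-pubertal, 1993 for nulliparous against pubertal and 26 for parous against nulliparous. The cause was not tested for these changes. With fewer or more genes tested, the filter at the 75th percentile gave 2362 for peri-pubertal against pre-pubertal and 0 for parous against nulliparous (431 at an unadjusted p under 0.05 in limma), no filter gave 4 for the latter and testing every probe set 12. Parous against nulliparous also gave 1 in a fit of only the groups compared.

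With covariates, again with no test of the cause, peri-pubertal against pre-pubertal gave 1987 (B cells), 310 (luminal epithelium) and 2014 (B cells and muscle). Pubertal against peri-pubertal gave 305 (B cells), 225 (luminal epithelium), 223 (muscle) and 435 (B cells and muscle). Parous against nulliparous gave 1 (luminal epithelium) and 4 (B cells and muscle). Stricter thresholds lower counts by construction. At an adjusted p under 0.01 the counts were 2230, 18, 148, 2245 and 0 for peri-pubertal against pre-pubertal, pubertal against peri-pubertal, nulliparous against pubertal, parous against lactation and parous against nulliparous. With a 2-fold minimum they were 612, 28, 69, 790 and 1 in that order, and 897 for lactation against pubertal. With fewer arrays, batch 1 alone gave 1 for pubertal against peri-pubertal, 250 for nulliparous against pubertal and 0 for parous against nulliparous. Batch 2 alone gave 643 for peri-pubertal against pre-pubertal, 0 for pubertal against peri-pubertal and 2383 for lactation against pubertal. Batch 3 alone, and all arrays without it, gave 0 for parous against nulliparous. Of the 82 list tests, 1 passed with an estimated correlation.

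Leaving out each array in turn gave 3000 to 3862 genes for peri-pubertal against pre-pubertal, 16 to 421 for pubertal against peri-pubertal, 204 to 426 for nulliparous against pubertal and 3508 to 4316 for lactation against pubertal. It gave 2992 to 3779 for parous against lactation, 0 to 8 for parous against nulliparous and 6873 to 7440 for the test of any stage. No paired analysis was possible because the replicate numbers only name samples in deposit order.

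These directions turned, with the cause not tested. With the B cell, luminal and both covariates, MHC class II in peri-pubertal against pre-pubertal glands was 0.214, 0.357 and 0.207, and Ciita 0.025, 0.136 and 0.023; RT1-DOb was 0.115 (B cells) and 0.122 (both). Lalba was -1.083 for peri-pubertal against pre-pubertal and 1.121 for parous against lactation with the luminal covariate. The T cell list for parous against lactation was -0.195 (B cells) and -0.145 (both), and for nulliparous against pubertal it was 0 to 0.721 with 1 array left out, the lowest without nulliparous array 3. The cell cycle list for pubertal against peri-pubertal was -0.576 to 0.034 with 1 array left out, the highest without peri-pubertal array 2, and the macrophage list was -0.038 within batch 2. For nulliparous against pubertal the clock list was -0.205 with no batch term. For lactation, Rpl23 was 0.413 with no batch term and Rpl3 0.039 with nulliparous glands as comparator. Of 299 called gene values, 87 lost their call with no batch term, 72 with the luminal covariate, 46 in fits of only the groups compared, 21 with the B cell covariate, and 0 without the intensity trend or with arrays centred. Signal over background could not be judged, as the table has no detection calls; the floor of 7.645, a median, left 10986 of 18166 genes.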

Other observations

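Some genes set 1 stage apart from each of the other 5 by at least 2-fold, with an adjusted p under 0.05 in each of the 5 limma comparisons; these counts and the genes named from them were chosen after the values were seen. Pre-pubertal glands had 51 genes above every other stage and 151 below. Besides Alox15 and Igf2, Mal, Ncmap, Pmp2 and Drp2 were at least 1.42, 1.35, 1.21 and 1.19 log2 units higher than in any other stage, while 1 of 9 genes (Mal) of the list for Schwann cells and nerve was. Of 19 luminal epithelium genes 17, and of 17 milk protein genes 8, were lowest in pre-pubertal glands. The 151 genes below every other stage included Plet1 (at least 2.83 lower), Btn1a1, a protein of the milk fat globule membrane (at least 2.42 lower), and the sodium channel subunits Scnn1b (2.07) and Scnn1g (1.96).

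Lactating glands had 199 genes above every other stage and 215 below. Lao1, an amino acid oxidase gene, was at least 3.65 log2 units higher, the sugar transporter gene Slc5a9 3.37, Arg2, an arginase gene, 3.02, and the complement gene C3 2.31. Rbp4 was at least 2.62 lower, the calcium-binding protein gene S100b 2.10 and the autotaxin gene Enpp2 1.87. Of 24 collagen and matrix genes 9, and of 20 white adipocyte genes 8, were lowest in lactation. Pubertal glands had 3 genes above every other stage, Pcsk2, Tll1 and Mx2, and peri-pubertal, nulliparous and parous glands had 0 genes above and 0 below every other stage. Parous and nulliparous glands were at least 2-fold apart at 1 called gene, and pubertal and peri-pubertal glands at 28. Few genes could therefore meet the rule in these stages. Over the other settings the pre-pubertal counts were 30 to 60 higher and 16 to 159 lower, the smallest with the luminal list mean as a covariate. Those of lactation were 154 to 226 higher and 182 to 332 lower. With each array left out in turn they were 45 to 56, 120 to 170, 170 to 248 and 178 to 294 in the same order. When stage labels were reassigned 100 times, the largest of the other counts was 0, 0, 1 and 1, and 1 of the 100 draws (the real one) reached each count. Reassigned groups mix animals of several stages, so a 2-fold gap from every other group was hardly possible in them. The draws therefore do not decide whether chance gave these 4 counts, which were chosen after the values were seen.

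Batch 3, prepared with the other kit from adult glands that the sample notes call more fatty, differed from batch 1 in some gene lists. Ribosomal protein genes were higher by a mean of 1.30 log2 units (camera adjusted p = 4.18e-05) and oxidative phosphorylation genes by 0.94 (adjusted p = 0.000191), each with adjusted p = 0.982 with an estimated correlation. White adipocyte genes differed by -0.09 (adjusted p = 0.96) and fatty acid synthesis genes by -1.19 (adjusted p = 0.101). All arrays of the batch used this kit, so kit and batch cannot be told apart.

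The mean of 29 cell cycle genes was 9.88 in peri-pubertal array 2 against 7.54 to 8.43 in the other 4, 9.57 in pre-pubertal array 8 and 9.47 in parous array 2. The animals were taken at random stages of the estrous cycle, per the labels, and the cycle stage of each is not given.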
